A study of Mus musculus with 12 samples.

How the data were processed

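RNA was taken from 12 CT26 tumours of the mouse cecum, 3 per group, and sequenced as poly(A)-selected, strand-marked paired-end libraries with molecular identifiers, per the labels' protocols. The deposited count matrix holds whole-number counts for 55401 genes, of which 26003 are 0 in every library, beside FPKM values that the authors deposited for the same genes and in 12 single-library tables. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR were used; their order, the counting step, its use of strand and the genome build are not given in the sources used here. Coordinates in the matrix equal those of GENCODE M21 (GRCm38) for 93.8% of genes, and at least 1 end is identical for 99.3%. Only the counts entered tests. The FPKM values served to check which library each single-library table holds.

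Matrix columns were matched to libraries by title. For 6 of the 12 libraries the title and source name contradict the treatment field. The single-library tables attached to those 6 carry the names of the opposite group in their headers, and all 12 tables equal the matrix column of the name in their header for all 55401 values. Column to title to source name, and single-library table to treatment field, both lead to the same treatment for each set of values. Column to title to treatment field, and single-library table to title and source name, both give the exchanged reading. That reading also needs the names in the headers themselves to be wrong. The labels contradict each other and do not settle which reading is right. The group names in the text follow the titles, and both readings are stated at each comparison that uses these groups. No pair of libraries agreed within counting noise (lowest chi-square per gene 110.7), so none was counted once for 2.

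Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 20009. Libraries were scaled by TMM, with factors from 0.848 to 1.067. One model with a term per group was fitted to all 12 libraries with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with 8 residual degrees of freedom. The common dispersion was 0.327, a biological coefficient of variation of 57.2% between the libraries of a group. The part that depth plays in the precision was not tested. The 7 comparisons were the 6 pairs of groups and the interaction. P-values are two-sided and adjusted by Benjamini-Hochberg over genes, with a threshold of 0.05; the SE of a log2 change is its size divided by the square root of the F statistic. The 21 gene lists and 20 lists of cell type markers were tested with camera (limma 3.58.1, preset correlation 0.01) and adjusted over the lists of their kind, and again with the correlation estimated from the data and with fry, whose directional p asks whether members move on balance one way and compares no list with other genes. List members were also adjusted over the list alone. Marker levels are the mean log2 CPM (prior count 2) over a list, compared by exact permutation with a smallest possible p of 0.1 for 3 against 3.

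The rule for named genes was set before the data were examined, as were the tests, lists and alternatives unless stated. It takes, among genes past the threshold with an average log2 CPM of at least 1, a named symbol and no overlap between the replicates of the groups, the 10 largest changes each way; up to 3 members of each list with members past the threshold; 8 genes in every comparison (Cd274, Cbs, Cth, Mpst, Eno1, Asns, Cd8a and Foxp3); and the 5 smallest p-values where fewer than 5 genes pass. Examples of list members with the smallest p were chosen after their values were seen. The alternatives were DESeq2 1.42.0 size factors, no filter, an average log2 CPM of at least 1, a DESeq2 Wald test, only the groups compared, the replicate number as a block, each library left out in turn, an estimated correlation and fry. Added after the data were seen were covariates for intestinal epithelium and skeletal muscle markers and a fit without 3 libraries in doubt, namely the 2 with the highest skeletal muscle markers (SARD + anti-PD-L1 replicate 3, and replicate 1 of the group named ND + anti-PD-L1) and the one with the largest share of ribosomal protein counts (replicate 3 of the group named SARD + IgG). The fry p-values of 7 list tests in the closing section were adjusted together by Benjamini-Hochberg, a step added after they were seen. They include covariate refits of the cholesterol synthesis and erythrocyte lists, which had already been called in these data. Their presence can lower the adjusted p of the other tests.

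The steps were tested on simulated data drawn from the real means. Counts were drawn independently for each gene, and only genes with an average log2 CPM of at least 1 were changed. The shares recovered cover such genes only. The simulated libraries lack the tissue structure shared within real ones, so their false calls may understate those in the real data. For SARD + anti-PD-L1 against ND + IgG, with 19183 simulated genes tested, 15% of genes changed 2-fold and 67% of those changed 4-fold were recovered, with 3 false among 85 calls. For the interaction 3% and 41% were recovered, with 1 false among 45 calls.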

Results

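The series measured transcript levels by RNA sequencing in CT26 tumours, a mouse colon cancer cell line grown in the cecum wall of mice. The mice received a normal diet (ND) or an amino acid restriction diet (SARD), together with a control antibody (IgG) or an antibody against PD-L1, the ligand of the T cell checkpoint receptor PD-1. The 12 libraries form 4 groups of 3. The summed gene counts per library ranged from 65578994 to 82449270. For 6 of the 12 libraries the labels contradict each other. The title and source name of 3 of them read ND + anti-PD-L1 while the treatment field reads SARD + IgG, and the other 3 carry the opposite pair. These are called the group named ND + anti-PD-L1 and the group named SARD + IgG, after the titles that match their matrix columns. The reading by name takes these names as the treatments and is also reached from the treatment fields through the tables attached to them. The exchanged reading swaps the treatments of the groups and needs the match of column to title together with the treatment field, or the attached table together with the title. It also needs the names in the headers of the matrix and of the attached tables to be wrong. The comparison of SARD + anti-PD-L1 with ND + IgG and the interaction do not depend on which reading is right. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure the spread between these samples.

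The first comparison asks what both treatments together change against neither. Ttc9 (ENSMUSG00000042734, chromosome 12, 81631249 to 81667557, GRCm38) was 2.94-fold lower in SARD + anti-PD-L1 tumours, at 6.29 ± 0.374 CPM (library-size-scaled counts, ± SD, n = 3) against 18.5 ± 1.59 CPM (SD, n = 3) in ND + IgG tumours. Its log2 change was -1.56 ± 0.18 (SE) and its adjusted p 0.0476. It was the single gene past the threshold of 0.05 among 20009 tested. The next smallest p-values belonged to Sema4b (log2 change -1.02 ± 0.14, adjusted p = 0.0944), Kpna2, an importin (-0.70 ± 0.10, 0.0944), Fam111a (1.63 ± 0.23, 0.0944) and Sgk1, a serum- and glucocorticoid-induced kinase (0.97 ± 0.14, 0.103), none of which passed. Cd274, which encodes PD-L1, had a log2 change of -0.23 ± 0.26 (adjusted p = 0.892). Cd8a, a cytotoxic T cell gene, had one of -0.75 ± 0.75 (0.860), and its 3 SARD + anti-PD-L1 libraries read 1.24, 3.03 and 18.95 CPM. The regulatory T cell factor Foxp3 (-0.95, 0.875), the amino acid starvation gene Asns (-0.29 ± 0.21, 0.756), the glycolytic gene Eno1 (0.02 ± 0.27, 0.997) and the sulfur amino acid enzymes Cbs (-0.23 ± 2.12, 0.995), Cth (0.09 ± 0.98, 0.996) and Mpst (0.39 ± 0.37, 0.843) did not pass.

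Of the 21 gene lists fixed beforehand, 8 were called in this comparison by camera with its preset correlation, all of them lower. Cytotoxic effector genes, the granzymes and their partners, had the lowest median of these, -1.79 on the log2 scale, with 19 of 20 members below 0 (camera adjusted p = 1.81e-13, adjusted p = 0.415 with an estimated correlation). Adjusted over the list alone, 5 of the 20 fell, and none did over all genes tested. Gzmc (log2 change -2.85 ± 0.79) and Gzme (-3.57 ± 1.07) are examples. The granzymes c to g are close paralogs whose reads may be shared. Cytotoxic effector genes averaged 1.80 ± 1.47 log2 CPM (SD, n = 3) in the SARD + anti-PD-L1 tumours, with libraries from 0.68 to 3.47, against 3.91 ± 0.98 in ND + IgG tumours. CD8 T cell markers, measured as Cd8a and Cd8b1 alone, averaged 1.29 ± 2.53 log2 CPM in SARD + anti-PD-L1, with libraries from -1.24 to 3.82, and 3.42 ± 0.18 in ND + IgG. In SARD + anti-PD-L1 replicates 1, 2 and 3, NK cell markers read -1.03, -0.23 and 1.34 against 1.11, 1.13 and 1.67 in those of ND + IgG, and general T cell markers -0.10, 1.22 and 3.31 against 2.71 ± 0.35. Inflammatory myeloid genes had a median of -1.33, with 18 of 19 members below 0 (camera adjusted p = 1.48e-09, adjusted p = 0.272 with an estimated correlation), and 1 member fell adjusted over the list alone. Ccl7 (-1.73 ± 0.41) and Ccl2 (-1.44 ± 0.42), monocyte chemokines, are examples. The other 6 called lists were checkpoint genes (median -0.57), type I interferon genes (-0.44), hypoxia genes (-0.42), glycolysis genes (-0.41), extracellular matrix genes (-0.24) and MHC class I genes (-0.21). Their adjusted p with an estimated correlation lay between 0.415 and 0.746. Beside these lists, erythrocyte markers averaged 1.88 ± 0.65 log2 CPM in SARD + anti-PD-L1 and 4.24 ± 0.75 in ND + IgG tumours. Mesothelium markers averaged 1.05 ± 1.40 and 3.11 ± 0.12, endothelial markers 2.84 ± 0.26 and 3.29 ± 0.12, regulatory T cell markers -0.85 ± 0.69 and 0.05 ± 0.04, and mast cell and eosinophil markers -0.86 ± 0.68 and -0.12 ± 0.15. The libraries did not overlap for these 5 of 20 marker lists, where chance gives 10% (exact two-sided permutation p = 0.1 for each, the smallest that 3 against 3 allows, and 0.4 adjusted over the lists). The call of Ttc9 was lost in the fits that left out any 1 of the ND + IgG, SARD + anti-PD-L1 or ND + anti-PD-L1-named libraries, or the first SARD + IgG-named library, with adjusted p from 0.0696 to 0.202 and a log2 change from -1.60 to -1.48. It was also lost without a filter on low counts (Ttc9 adjusted p = 0.0709), with only the groups compared (0.264), with intestinal epithelium (0.166) or skeletal muscle markers (0.0814) as a covariate and without the 3 libraries in doubt (0.148), in a range of 1.71e-15 to 0.264 over all alternatives run. The count of genes was 2 without replicate 2 named SARD + IgG, 1 without its replicate 3 or ND + IgG replicate 3 and 0 without any other single library. A Wald test in DESeq2 called 295 genes where the edgeR quasi-likelihood test called 1. That run also took in all genes with a count and used its own size factors, so the test is not the only difference.

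**Figure D1:**
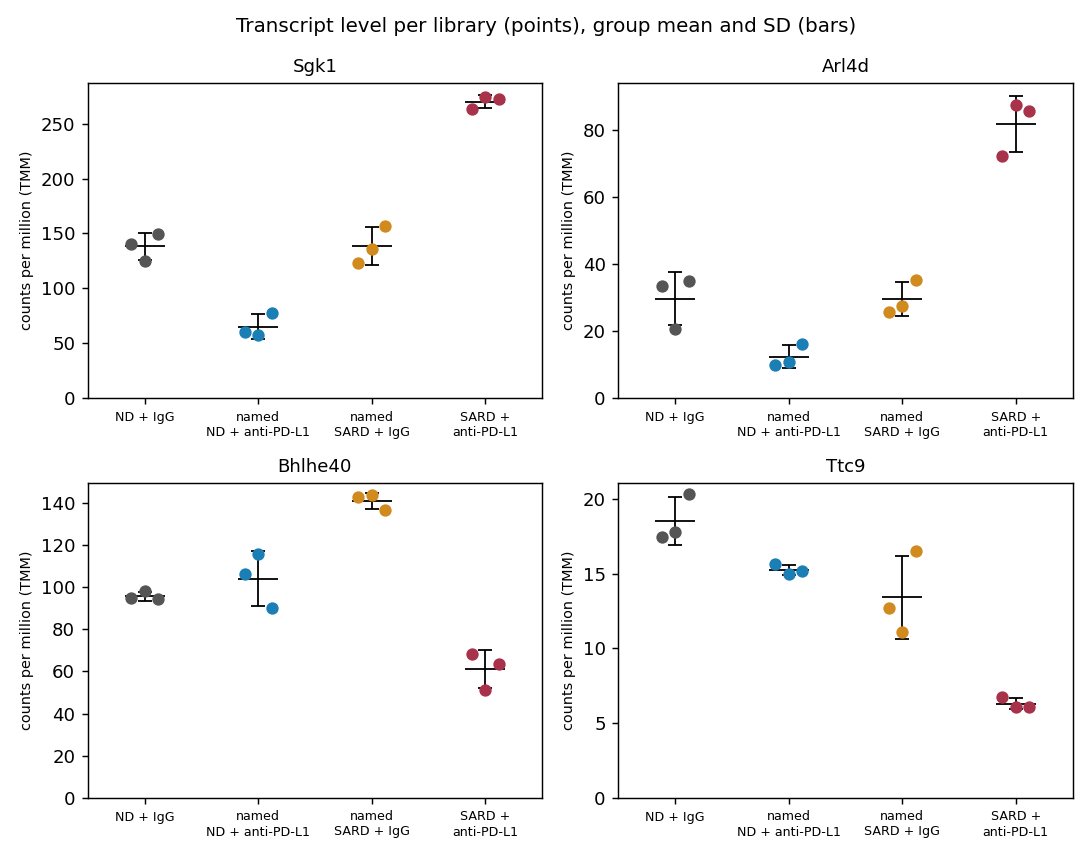
CPM after TMM scaling (vertical axes, linear) of Sgk1, Arl4d, Bhlhe40 and Ttc9 in each of the 12 libraries (points), with the group mean (long bar) and SD (whiskers), n = 3 per group; the 2 middle groups carry conflicting labels and stand under the names of their titles. Sgk1 lies at 270 ± 5.98 CPM in SARD + anti-PD-L1 and at 64.9 ± 11.2 CPM in the group named ND + anti-PD-L1.

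The interaction asks whether the response to one treatment differs with the other, and its value is the same whichever way the conflicting labels are read. Sgk1 (ENSMUSG00000019970, chromosome 10, 21882184 to 21999893) was the single gene past the threshold, with an interaction of 2.05 ± 0.20 on the log2 scale (SE, adjusted p = 0.0104). Its level was 138 ± 12.5 CPM in ND + IgG tumours, 64.9 ± 11.2 CPM in the group named ND + anti-PD-L1, 139 ± 17.2 CPM in the group named SARD + IgG and 270 ± 5.98 CPM in SARD + anti-PD-L1 tumours (SD, n = 3 each). The next smallest p-values belonged to Arl4d, a small GTPase of the ADP-ribosylation factor family (2.75 ± 0.34, adjusted p = 0.0616), the circadian and hypoxia-linked repressor Bhlhe40 (-1.33 ± 0.18, 0.0988), Foxred2 (1.85 ± 0.27, 0.122) and Hmox2 (-1.03 ± 0.16, 0.232), none of which passed. Cd274 (0.42 ± 0.36, 0.773), Cd8a (0.19 ± 1.05, 0.979) and Asns (-0.09 ± 0.30, 0.958) did not pass either, nor did Foxp3, Eno1, Cbs, Cth and Mpst (adjusted p from 0.644 to 0.960). Camera called 12 of the 21 lists, 11 of them lower. Inflammatory myeloid genes had a median of -1.27 (camera adjusted p = 1.03e-05, adjusted p = 0.812 with an estimated correlation), and no member passed over all genes. Hypoxia genes (median -0.63) and glycolysis genes (-0.62) were also lower (adjusted p = 0.835 with an estimated correlation for each). Erythrocyte markers had a median interaction of -3.44 (camera adjusted p over the marker lists 9.62e-14, adjusted p = 0.119 with an estimated correlation). Of the 20 marker lists camera called 8, all lower: besides erythrocyte, these were endothelial (median -1.06, 12 of 12 members below 0), dendritic cell (-0.99, 11 of 11), mast cell and eosinophil (5 of 7), neutrophil (-1.33, 10 of 11), fibroblast (-0.50, 11 of 11), smooth muscle (-1.64, 9 of 10) and acinar pancreas markers (6 of 6). Their adjusted p with an estimated correlation lay between 0.418 and 0.671. Acinar pancreas markers were at 7.49 and 2.95 log2 CPM in replicates 1 and 2 named ND + anti-PD-L1 and at or below 0.97 in the other 10 libraries. The Sgk1 call was lost without SARD + anti-PD-L1 replicate 2 (adjusted p = 0.0553, log2 2.04) with skeletal muscle markers as a covariate (0.0622, log2 2.07) and without the 3 libraries in doubt (0.142, log2 2.09), in a range of 6.06e-17 to 0.142 over all alternatives run. The count of genes was 3, 2 and 3 without ND + IgG replicates 1, 2 and 3, 2 and 3 without replicates 1 and 3 named ND + anti-PD-L1, 2 and 3 without replicates 2 and 3 named SARD + IgG. It was 0 without SARD + anti-PD-L1 replicate 2 and 209 by DESeq2.

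SARD + anti-PD-L1 tumours against the group named ND + anti-PD-L1 gave the largest count of any comparison, 110 genes, of which 45 rose and 65 fell. By name this is the effect of the diet under anti-PD-L1, and under the exchanged reading it is the effect of anti-PD-L1 under SARD. Sgk1 rose 4.16-fold (log2 change 2.06 ± 0.14, adjusted p = 0.000388) and Arl4d 6.67-fold (2.74 ± 0.25, 0.0033), from 12.2 ± 3.42 to 81.6 ± 8.3 CPM. Lyve1, a hyaluronan receptor of lymphatic vessels and some macrophages and a member of the alternative macrophage list, rose 4.06-fold, from 27.6 ± 3.05 to 112 ± 26.5 CPM (adjusted p = 0.0166). Others among the 10 largest rises were Gadd45a, a DNA damage and stress gene (5.72-fold), Fam171b (6.38-fold), Zc3h6 (5.15-fold), Pygo2, a Wnt pathway cofactor (5.11-fold), Edn1, endothelin 1 (4.56-fold), Spsb1 (4.35-fold) and Arsg, a lysosomal sulfatase (4.17-fold), with adjusted p from 0.0239 to 0.0497. The clock output gene Dbp fell 4.54-fold (log2 change -2.18 ± 0.38, adjusted p = 0.0397) and Ier5l 4.64-fold (-2.21 ± 0.30, 0.0173). Fam167b, Kctd11, Cdc42ep2, Yae1d1, Hic1, Pcyox1l, the monocarboxylate transporter Slc16a13 and Trib1 fell between 2.81-fold and 3.11-fold, with adjusted p from 0.0149 to 0.0484.

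Cholesterol synthesis genes were lower in the same comparison, at a mean of 4.98 ± 0.28 log2 CPM in SARD + anti-PD-L1 against 5.74 ± 0.06. ND + IgG stood at 5.10 ± 0.40, near SARD + anti-PD-L1. The difference thus takes in a high level in the group named ND + anti-PD-L1. Of 23 measured members, 3 fell over all genes tested and 18 fell adjusted over the list alone, with a median of -0.69 (camera adjusted p = 1.09e-15, adjusted p = 0.319 with an estimated correlation, fry adjusted p = 0.0376). The 3 were Cyp51 (log2 change -1.42 ± 0.26, adjusted p = 0.0466), Acat2 (-1.14 ± 0.20, 0.0441) and Nsdhl (-0.84 ± 0.16, 0.0484), enzymes of sterol synthesis or its acetoacetyl-CoA supply. Type I interferon genes had a median of -0.71, and 12 of 26 fell adjusted over the list alone (adjusted p = 0.497 with an estimated correlation). Inflammatory myeloid genes had a median of -1.35, and 6 of 19 fell adjusted over the list alone (adjusted p = 0.319 with an estimated correlation). Single members of 2 further lists fell over all genes tested: Vsir, which encodes the checkpoint protein VISTA (-1.19 ± 0.22, adjusted p = 0.0492) and Bhlhe40 of the hypoxia list (-0.77 ± 0.13, 0.0361). Cd274 (-0.02 ± 0.26, 0.983), Cd8a (-0.95 ± 0.75, 0.565), Foxp3 (-1.24, 0.580), Asns (0.02 ± 0.21, 0.976), Eno1 (-0.19 ± 0.27, 0.790), Cbs (1.60 ± 2.19, 0.780), Cth (0.64 ± 0.99, 0.812) and Mpst (0.51 ± 0.37, 0.520) did not pass. Skeletal muscle markers stood at 5.72 ± 1.12 log2 CPM in the group named ND + anti-PD-L1, at -1.74 ± 0.82 in ND + IgG and at -1.89 ± 0.72 in the group named SARD + IgG. In the SARD + anti-PD-L1 tumours 1 library read 6.79 and the others -1.71 and -0.91. Acinar pancreas markers stood at 7.49, 2.95 and -3.17 log2 CPM in the 3 libraries named ND + anti-PD-L1. Endothelial markers averaged 2.84 ± 0.26 in SARD + anti-PD-L1 tumours and 3.42 ± 0.14 in the group named ND + anti-PD-L1, mesothelium markers 1.05 ± 1.40 and 2.45 ± 0.51, and erythrocyte markers 1.88 ± 0.65 and 3.41 ± 0.85, without overlap (exact two-sided permutation p = 0.1 for each, 0.5 adjusted over the lists). With skeletal muscle markers as a covariate 3 genes were called, with intestinal epithelium markers 66, without a filter on low counts 61, at an average log2 CPM of at least 1 246, and without the 3 libraries in doubt 4. The muscle covariate cannot decide whether muscle accounts for the calls. Its markers were high in every library named ND + anti-PD-L1, so it leans on SARD + anti-PD-L1 replicate 3. DESeq2 called 1577 genes. Leaving out 1 library gave 5, 2 and 45 genes for replicates 1, 2 and 3 named ND + anti-PD-L1, 9, 2 and 259 for those of SARD + anti-PD-L1. It gave 66 and 68 for replicates 1 and 3 named SARD + IgG, and 246 and 37 for replicates 1 and 3 of ND + IgG.

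**Figure D2:**
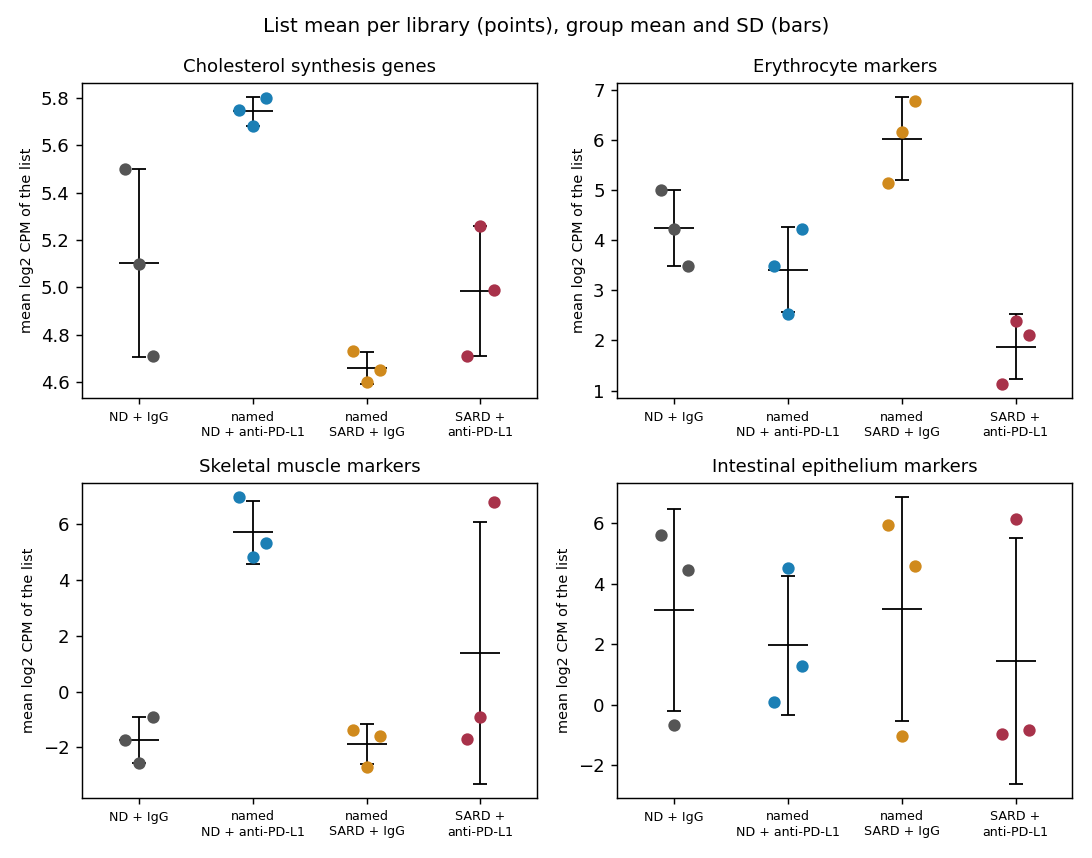
Mean log2 CPM over the members of 4 gene lists (vertical axes, log2 scale, each with its own range) in each of the 12 libraries (points), with the group mean (long bar) and SD (whiskers), n = 3 per group. Cholesterol synthesis genes stand at 5.74 ± 0.06 in the group named ND + anti-PD-L1 and 4.66 ± 0.07 in the group named SARD + IgG, and intestinal epithelium markers spread within every group.

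Between the groups with conflicting labels, which each received 1 of the 2 treatments, cholesterol synthesis genes had the smallest camera p of the 21 lists. The change is from anti-PD-L1 alone to SARD alone by name, and from SARD alone to anti-PD-L1 alone under the exchanged reading. Cholesterol synthesis genes were lower in the group named SARD + IgG than in the group named ND + anti-PD-L1, with a median log2 change of -1.11 over 23 members, 22 of them below 0. Their mean was 4.66 ± 0.07 against 5.74 ± 0.06 log2 CPM, with ND + IgG between at 5.10 ± 0.40. Adjusted over the list alone, 21 members fell, and over all genes tested 2 did. Acat2 fell 3.11-fold, from 76.8 ± 2.87 to 24.7 ± 8.2 CPM (log2 change -1.64 ± 0.21, adjusted p = 0.0282), and Insig1, a sterol-sensing regulator of the pathway, 2.51-fold (-1.33 ± 0.18, 0.0390). The list was called by camera (adjusted p = 6.87e-36), with an estimated correlation (adjusted p = 0.0489) and by fry (0.00326). In all, 9 genes passed in edgeR, 4 higher and 5 lower, and 1407 in DESeq2. Klf9, a glucocorticoid- and thyroid-hormone-induced factor, rose 2.57-fold (1.36 ± 0.17, adjusted p = 0.0282), Sgk1 2.13-fold (1.09 ± 0.14, 0.0282), the clock-linked repressor Nfil3 2.69-fold (1.43 ± 0.20, 0.0390) and Pygo2 7.26-fold (2.86 ± 0.36, 0.0282). The cell cycle repressor E2f8 (-1.19 ± 0.15), the ubiquitin ligase gene Ttc3 (-0.83 ± 0.10) and the galactosyltransferase gene B4galt5 (-1.25 ± 0.17) fell, with adjusted p from 0.0282 to 0.0327. Ribosomal protein genes had a median of 0.60, and 32 of 36 rose adjusted over the list alone (camera adjusted p = 3.76e-21, adjusted p = 0.412 with an estimated correlation). The share of counts in ribosomal protein genes was 12.6, 13.9 and 18.0% in the libraries named SARD + IgG and 10.7 to 11.6% in those named ND + anti-PD-L1. Interferon gamma targets (median -0.90, 5 of 28 lower adjusted over the list alone) and amino acid response genes (median 0.44, 5 of 37 higher adjusted over the list alone) had adjusted p = 0.412 and 0.417 with an estimated correlation. The mean over amino acid response genes was 5.39, 6.09 and 5.61 log2 CPM in the libraries named SARD + IgG. In those named ND + anti-PD-L1 it was 5.13, 5.21 and 5.39, so the groups touched. Asns had a log2 change of 0.44 ± 0.21 (adjusted p = 0.321), Cd8a of -1.34 ± 0.76 (0.393) and Cd274 of -0.23 ± 0.26 (0.702). Foxp3, Eno1, Cbs, Cth and Mpst did not pass (adjusted p from 0.633 to 0.823). Skeletal muscle markers were 7.61 lower on the log2 scale in the group named SARD + IgG and erythrocyte markers 2.61 higher, without overlap. CD8 T cell markers (2.35 ± 0.36 against 3.54 ± 0.65 log2 CPM) and macrophage markers (6.81 ± 0.16 against 7.11 ± 0.11) were lower without overlap (exact two-sided permutation p = 0.1 for each of the 4 lists, 0.5 adjusted over the lists). The CD8 T cell list is Cd8a and Cd8b1, so it is not separate from the Cd8a value above. None of the 9 genes passed with intestinal epithelium markers (adjusted p from 0.0564 to 0.0703) or skeletal muscle markers (0.296 to 0.339) as a covariate, where 0 genes passed in all, or without the 3 libraries in doubt (0.339 to 0.394), where 2 others did. The muscle covariate cannot decide on muscle here, since its markers separated the groups without overlap. With only the groups compared 4 genes passed, of these 9 only Pygo2, and at an average log2 CPM of at least 1 33 passed. The count of 9 fell to 1 and 0 without replicates 1 and 2 named ND + anti-PD-L1, to 2 without replicate 3 named SARD + IgG and to 0 without SARD + anti-PD-L1 replicate 2. It was 182 and 21 without replicates 1 and 2 named SARD + IgG, 45 and 17 without ND + IgG replicates 1 and 3 and 22 without SARD + anti-PD-L1 replicate 3.

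Erythrocyte transcripts were low in SARD + anti-PD-L1 tumours against the group named SARD + IgG. By name this is the effect of anti-PD-L1 under SARD, and under the exchanged reading it is the effect of the diet under anti-PD-L1. All 5 measured erythrocyte markers were lower, with a median log2 change of -4.18, and all 5 fell adjusted over the list alone while none passed over all genes tested. Their mean was 1.88 ± 0.65 log2 CPM against 6.02 ± 0.83, with ND + IgG between at 4.24 ± 0.75. Hbb-bs, a beta globin gene, stood at 13.3 ± 3.18 CPM against 242 ± 142 CPM (log2 change -4.18 ± 0.55, adjusted p = 0.106), and the alpha globin genes Hba-a1 (-4.01 ± 0.56, 0.106) and Hba-a2 (-4.08 ± 0.59, 0.106) stood beside it. Globin copies share reads. Over the 20 marker lists, erythrocyte markers were called by camera (adjusted p = 1.97e-25), with an estimated correlation (adjusted p = 0.0200) and by fry (0.0120). Bhlhe40, at 61 ± 8.95 CPM against 141 ± 3.77 CPM, was the single gene past the threshold and fell 2.31-fold (-1.21 ± 0.13, adjusted p = 0.0295). Sgk1 had a log2 change of 0.96 ± 0.14 (adjusted p = 0.106). Endothelial markers averaged 2.84 ± 0.26 log2 CPM against 3.58 ± 0.47 and mesothelium markers 1.05 ± 1.40 against 3.23 ± 0.89, without overlap, as for erythrocyte markers (exact two-sided permutation p = 0.1 for each, 0.667 adjusted over the lists). Of the 21 gene lists camera called 11, 2 of them higher, and none with an estimated correlation. Hypoxia genes had a median of -0.72 and 4 of 20 fell adjusted over the list alone (adjusted p = 0.586 with an estimated correlation). Cholesterol synthesis genes had a median of 0.33 and 2 of 23 rose adjusted over the list alone (adjusted p = 0.586 with an estimated correlation). Cd274 (0.21 ± 0.26, 0.781), Cd8a (0.39 ± 0.75, 0.878), Foxp3 (-0.66, 0.835) and Asns (-0.41 ± 0.21, 0.432) did not pass, nor did Eno1, Cbs, Cth and Mpst (adjusted p from 0.535 to 0.995). The Bhlhe40 call held without replicates 1 and 3 named SARD + IgG and replicate 3 named ND + anti-PD-L1 and was lost without any other single library (adjusted p from 0.0560 to 0.142, log2 change from -1.29 to -1.10). Bhlhe40 also missed the threshold with skeletal muscle markers as a covariate (adjusted p = 0.104), with only the groups compared (0.319) and without the 3 libraries in doubt (0.308), in a range of 5.48e-13 to 0.319 over all alternatives run. The count of genes was 7 without replicate 1 named SARD + IgG, 3 without its replicate 3 4 without replicate 3 named ND + anti-PD-L1 and 0 without any other single library. DESeq2 called 557 genes.

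Against ND + IgG, neither group with conflicting labels had a gene past the threshold in edgeR. The group named ND + anti-PD-L1 shows the effect of the antibody alone by name and of the diet alone under the exchanged reading. It had 1269 genes at an unadjusted p under 0.05, where chance gives about 1000, and DESeq2 called 143. The smallest p-values were those of Sgk1 (log2 change -1.09 ± 0.14, adjusted p = 0.117), Pygo2 (-2.69 ± 0.36, 0.117), Dbp (2.44 ± 0.38, 0.329), Fam111a (1.38 ± 0.23, 0.367) and Esyt3 (-1.86 ± 0.31, 0.367). Cholesterol synthesis genes had a median of 0.57, with 15 of 23 members higher adjusted over the list alone (camera adjusted p = 9.29e-23, adjusted p = 0.146 with an estimated correlation). Sgk1, Pygo2, Dbp and cholesterol synthesis genes also differed between this group and SARD + anti-PD-L1. Both comparisons share the libraries of this group, so they are not separate evidence. Amino acid response genes had a median of -0.38 (camera adjusted p = 3.24e-07, adjusted p = 0.791 with an estimated correlation), and Asns a log2 change of -0.32 ± 0.21 (0.868). Cd274, Cd8a, Foxp3, Eno1, Cbs, Cth and Mpst did not pass (adjusted p from 0.942 to 0.988). Skeletal muscle markers stood 7.46 higher on the log2 scale, dendritic cell markers 0.83 higher and regulatory T cell markers at -0.18 ± 0.13 against 0.05 ± 0.04, without overlap (exact two-sided permutation p = 0.1 for each, 0.667 adjusted over the lists). In the regulatory T cell list Foxp3 (log2 change 0.29 ± 0.99) and Cd4 (0.50 ± 0.70) lay above 0. The other members lay below, the furthest being Ctla4 (-1.25 ± 0.65) and Il2ra (-1.20 ± 0.59). One or 2 genes passed without ND + IgG replicate 1 (1) or 3 (2), without replicate 1 (1) or 3 (2) named ND + anti-PD-L1, without replicate 2 named SARD + IgG (1) and without SARD + anti-PD-L1 replicate 3 (1).

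The group named SARD + IgG shows the effect of the diet alone by name and of the antibody alone under the exchanged reading. Against ND + IgG it had 1208 genes at an unadjusted p under 0.05 and 80 called by DESeq2. The smallest p-values were those of Ttc3 (log2 change -0.83 ± 0.10, adjusted p = 0.109), Wdr81 (-1.39 ± 0.23, 0.576), the unnamed gene model Gm15122 (-7.45 ± 1.11, 0.576), Gtf3c1 (-0.76 ± 0.13, 0.599) and Sox4, a transcription factor (1.11 ± 0.20, 0.664). Ribosomal protein genes had a median of 0.40, with 35 of 36 members above 0 and none passing adjusted over the list alone (camera adjusted p = 1.39e-17, adjusted p = 0.455 with an estimated correlation). The list mean was 10.55, 10.84 and 11.35 log2 CPM in the libraries named SARD + IgG and 10.47, 10.66 and 10.54 in ND + IgG. Replicate 3 named SARD + IgG thus carried most of the difference. Cholesterol synthesis genes had a median of -0.51, and 8 of 23 fell adjusted over the list alone (camera adjusted p = 4.88e-13, adjusted p = 0.455 with an estimated correlation). Interferon gamma targets had a median of -0.56 (camera adjusted p = 2.53e-07, adjusted p = 0.455 with an estimated correlation). Erythrocyte markers averaged 6.02 ± 0.83 log2 CPM against 4.24 ± 0.75 in ND + IgG, and CD8 T cell markers (Cd8a and Cd8b1) 2.35 ± 0.36 against 3.42 ± 0.18, without overlap (exact two-sided permutation p = 0.1 for each, 1 adjusted over the lists). Asns (0.12 ± 0.21, 0.971) and Cd8a (-1.14 ± 0.75, 0.868) did not pass, nor did Cd274, Foxp3, Eno1, Cbs, Cth and Mpst (adjusted p from 0.846 to 0.999). One gene passed without ND + IgG replicate 3 (1), and 2 without replicate 3 named SARD + IgG (2).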

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

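The tests of the unseen glucocorticoid and SREBP lists, of the covariates and of single libraries were written before their results were seen; the endothelial test, the counts over other splits of the libraries and the adjustment of 7 fry p-values together were chosen after. The gene Sgk1 and 12 gene lists are listed here because the response to one treatment differed with the other by the test of the interaction. Sgk1 had an interaction of 2.05 on the log2 scale. The median interactions of the lists were -0.30 for type I interferon genes, -0.82 for cytotoxic effectors, -1.27 for inflammatory myeloid genes, -0.63 for hypoxia genes, -0.62 for glycolysis genes, -0.10 for oxidative phosphorylation genes, -0.22 for cholesterol synthesis genes, 0.18 for cell cycle genes, -0.34 for unfolded protein response genes, -0.33 for p53 targets, -0.33 for extracellular matrix genes and -0.22 for ribosomal protein genes. None of the 12 was called with an estimated correlation.

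Random regroupings show how far these counts go. For the interaction, 17 of 100 splits of the libraries, the real one included, gave at least the 1 gene of the real split, and the highest other split gave 306. For lists, 29 of 100 gave at least its 12, and the highest other gave 17. Chance is excluded for neither count. The split with 306 genes sets the 6 libraries with high intestinal epithelium markers against the 6 with low ones, which points to a structure of the samples that crosses the groups. The pairs of groups allow 10 splits each, too few for a share under 0.05. For SARD + anti-PD-L1 against ND + IgG, 3 of 10 splits gave as many genes (real 1, highest other 1) and 7 as many lists (8 and 16). Against the group named ND + anti-PD-L1, 1 of 10 did for genes (110 and 1) and 5 for lists (12 and 16). Against the group named SARD + IgG, 2 did for genes (1 and 4) and 6 for lists (11 and 13). Between the groups with conflicting labels, 1 did for genes (9 and 1) and 6 for lists (9 and 14). Against ND + IgG, neither group with conflicting labels had a gene called in the real split. Every split therefore reaches that count of 0 (highest other 1 for each), and the gene counts decide nothing there. For lists, the group named ND + anti-PD-L1 gave 5 (9 and 13) and the group named SARD + IgG 7 (10 and 14).

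The Sgk1 interaction was weighed against tissue carried over and single libraries. It was 2.05 with intestinal epithelium markers as a covariate (2.055 unrounded, adjusted p = 0.0275) and 2.07 ± 0.22 with skeletal muscle markers (2.05 ± 0.20 without), where the call ended (adjusted p = 0.0622) as the SE grew while the change did not shrink. The lowest value over 12 fits without 1 library was 1.99, so the tables argue against gut wall or a single library as the whole of the change. The muscle covariate cannot decide on muscle. Muscle markers were high in every library named ND + anti-PD-L1, so the covariate leans on SARD + anti-PD-L1 replicate 3. Over the alternatives adjusted p ranged from 6.06e-17 to 0.142. A hypothesis is that glucocorticoid-induced genes as a class differ: 17 such genes listed without sight of their values had a median interaction of 0.42, with 13 above 0 (limma's fry, adjusted p = 0.0668 over 7 list tests), and 0.36 when Per2, whose values had been seen, is kept in the list. The test met its stated criterion of 0.05 before adjustment and missed it after, so this stays weak. The design names diet and antibody; stress, time of day and hormone levels were not measured and stay open.

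Cholesterol synthesis genes between the groups with conflicting labels kept a median of -1.15 with intestinal epithelium markers as a covariate (fry, adjusted p = 0.00224) and -1.10 with skeletal muscle markers (adjusted p = 0.0117). The list had been called in these same libraries, so these p-values are no separate support. Only the size of the medians bears on the covariates. Of the fits without 1 library, only those that left out a library of these groups bear on the difference. Their medians ran from -1.19 to -1.05. The muscle covariate cannot decide on muscle. Muscle markers lay from 4.84 to 6.98 log2 CPM in the group named ND + anti-PD-L1 and from -2.70 to -1.37 in the group named SARD + IgG. The covariate thus leans on SARD + anti-PD-L1 replicate 3, at 6.79 beside -1.71 and -0.91 in its group. The other values argue against gut wall or a single library as the whole of the difference. So do the libraries for acinar pancreas: its markers ran 7.49, 2.95 and -3.17 log2 CPM over the libraries named ND + anti-PD-L1 while cholesterol synthesis genes stood at 5.75, 5.68 and 5.80, and the median without the library at 7.49 was -1.10. A hypothesis is a difference in SREBP-dependent lipid genes as a class: 17 other targets listed without sight of their values had a median of -0.61, with 16 below 0 (fry, adjusted p = 0.00224). Which treatment goes with the higher level depends on the conflicting labels.

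Haemoglobin transcripts were low in SARD + anti-PD-L1 tumours against the group named SARD + IgG. Erythrocyte markers averaged 1.88 ± 0.65 and 6.02 ± 0.83 log2 CPM in these groups, with ND + IgG between them at 4.24 ± 0.75. The difference thus takes in levels on both sides of ND + IgG, and a raised level in the group named SARD + IgG was not tested. The median of the erythrocyte markers was -4.17 with intestinal epithelium markers as a covariate (fry, adjusted p = 0.00322), and this size argues against gut wall. The p-value is no separate support, since the list had been called in the same libraries. Less blood in the dissected piece cannot be told apart from other causes: other erythroid genes had a median of -0.068, but several of them, such as Ubb and Tfrc, are also expressed by tumour cells, and 5 of 7 platelet genes were lower (median -1.171, SE 1.249; fry, adjusted p = 0.0819), with a list mean of -0.86, -0.66 and -0.71 log2 CPM against -0.46, -0.76 and 0.82, so that 1 library carries most of the difference. The test asked that the erythroid median lie above -1 by more than its SE of 0.466, which it did, and that no platelet gene fall. This SE and that of the platelet median come from the spread over the genes of a list, 11 for the erythroid one, and not over libraries. Counting any lower value as a fall was settled after the values were seen and changed the outcome. With only genes past the threshold counted, the written rule would have excluded less blood, on an SE that treats genes as independent. Fewer vessels cannot be told apart either, with endothelial markers at a median of -0.82 and an adjusted fry p of 0.0841.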

How the results depend on the processing

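The covariates and the fit without 3 libraries in doubt were chosen after the data were seen. The spread between libraries of a group was wide (biological coefficient of variation 57.2%), and no fit varied the depth. Of the alternatives for list calls, 1226 kept their side of the threshold, 263 lost it and 2 turned: with skeletal muscle markers as a covariate, interferon gamma targets (adjusted p = 0.0198) and type I interferon genes (0.00716) were lower, not higher, in the group named ND + anti-PD-L1 against ND + IgG. The muscle covariate cannot decide that direction. Muscle markers lay from 4.84 to 6.98 log2 CPM in the group named ND + anti-PD-L1 and from -2.57 to -0.93 in ND + IgG. The covariate thus leans on SARD + anti-PD-L1 replicate 3, at 6.79. Of those for named genes, 1884 were the same, 395 lost the call, 37 gained one, 64 moved and 0 turned. The named genes include many that were not past the threshold to begin with. Such a gene counts as the same if it stays uncalled with its change within the SE. The 1884 therefore do not give the share of calls that held. The cause was not tested for any change unless stated.

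Genes changed, in the order SARD + anti-PD-L1 against ND + IgG, the groups named ND + anti-PD-L1 and SARD + IgG against ND + IgG, SARD + anti-PD-L1 against each of these 2, the second against the first, and the interaction, were 1, 0, 0, 110, 1, 9 and 1. The DESeq2 Wald test, run on all genes with a count and with its own size factors, gave 295, 143, 80, 1577, 557, 1407 and 209. Without a filter the first was 0 and the fourth 61, with more genes tested; at an average log2 CPM of at least 1 the fourth was 246, the sixth 33 and the interaction 2, with fewer. With only the groups compared, and fewer libraries to estimate the spread, they were 0, 1, 1, 120, 0 and 4. With intestinal epithelium markers as a covariate the first was 0, the fourth 66, the fifth 2 and the sixth 0. With skeletal muscle markers they were 0, 3, 0 and 0, and the interaction 0, under the limit of that covariate given above. Without the 3 libraries in doubt they were 3, 1, 1, 4, 1, 2 and 2. Leaving out 1 library gave 0 to 2, 0 to 2, 0 to 2, 2 to 259, 0 to 7, 0 to 182 and 0 to 3.

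Replicate numbers do not pair the libraries: same-numbered libraries correlated from -0.41 to 0.36 (median -0.1), and 4 of 12 correlated best with their own number. With the replicate block the first count was 0, the fourth 12, the fifth 0, the sixth 0 and the interaction 2.

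Gene lists changed, in the same order, were 8, 9, 10, 12, 11, 9 and 12. With an estimated correlation they were 0, 0, 0, 0, 0, 1 and 0, and with fry 0, 0, 0, 1, 0, 1 and 0. With skeletal muscle markers as a covariate the fourth was 6. Leaving out 1 library gave 7 to 12, 7 to 12, 8 to 15, 11 to 14, 9 to 13, 7 to 12 and 7 to 15. The pseudocount alternative was not run, since it applies to FPKM.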

Other observations

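The clock genes given here were chosen after their values were seen. In the group named ND + anti-PD-L1 against ND + IgG, Dbp (log2 change 2.44 ± 0.38), Tef (1.11 ± 0.28), Per3 (1.09 ± 0.34) and Per2 (0.88 ± 0.29) had higher values and Arntl (-1.04 ± 0.22) and Nfil3 (-0.96 ± 0.20) lower ones, and none passed over all genes in edgeR (adjusted p from 0.329 to 0.740). Dbp lay at 102.87, 61.11 and 32.44 CPM in the 3 libraries named ND + anti-PD-L1 and between 9.09 and 16.63 CPM in the other 9. The mean over Dbp, Tef, Hlf, Per2 and Per3 overlapped, at 4.65, 4.44 and 3.33 log2 CPM in those 3 libraries and between 1.72 and 3.35 in the other 9. The mean over Arntl, Npas2, Clock and Nfil3 did not overlap, at 2.53, 2.68 and 2.30 log2 CPM in those 3 and between 2.77 and 3.83 in the other 9. The labels give no time of dissection.

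Intestinal epithelium markers spread within every group. In 6 libraries, ND + IgG 1 and 3, replicate 2 named ND + anti-PD-L1, replicates 1 and 3 named SARD + IgG and SARD + anti-PD-L1 2, their mean lay between 4.46 and 6.13 log2 CPM, and in the other 6 between -1.04 and 1.29. The first principal component held 23.8% of the variance and separated the same libraries. It ran from -103.2 to -35.1 in the first 6 and from 47.9 to 74.7 in the other 6. Skeletal muscle transcripts stood in 4 libraries: Acta1, skeletal muscle actin, lay at 357.58, 87.95 and 174.58 CPM in the libraries named ND + anti-PD-L1 and at 300.25 CPM in SARD + anti-PD-L1 3, and at or below 0.92 CPM in the other 8. Prss2, an acinar trypsinogen, lay at 161.46 CPM in replicate 1 named ND + anti-PD-L1, 10.1 CPM in its replicate 2 and 2.15 CPM in replicate 2 named SARD + IgG, and at or below 0.4 CPM elsewhere.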
